A study of Mus musculus with 6 samples.

How the data were processed

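Gene expression was measured in LKS+ cells from mice, the marrow cells that lack mature-lineage markers and carry high c-Kit and Sca-1 on their surface, a population that holds hematopoietic stem cells and multipotent progenitors. Per the labels' protocols, at least 20000 cells per mouse were sorted by flow cytometry at a purity above 90%. RNA was taken from a lysate with a micro-scale column kit, amplified linearly with the Nugen Ovation system, turned into biotin-labelled cDNA and hybridized to Affymetrix Mouse Genome 430 2.0 arrays, also per the labels. There were 3 arrays from wild-type (WT) mice and 3 from Apcmin mice, grouped by the genotype in their titles. The labels count cells per mouse, and each array was treated as 1 mouse, although no label names the animals.

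The authors deposited 1 normalized intensity per probe set and array, on a linear scale. RMA is named in the submitters' processing notes, and its version and background step are not given in the sources used here. RMA usually returns log2 values, which the analysis plan had assumed. The deposited intensity values were all positive and not on a log scale, so log2 was taken with no pseudocount, as the plan provided. The 6 columns of the table matched the 6 samples, and no scanner file was used here. The lowest intensities have no detection call, and differences between dim probe sets can come from background. The number of arrays limits the precision. The median 95% confidence half-width of a log2 difference was 0.50 over all probe sets and 0.41 over the 15155 probe sets with a mean log2 intensity of at least 6.

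Of 45101 probe sets, 64 controls were left out and 45037 were tested. Exactly 1 gene symbol was listed for 34945 probe sets, several for 932 and none for 9160. Symbols were looked up through their Entrez identifiers in a RefSeq table of the assembly GRCm38.p6, where 34741 matched and 0 changed. A gene was represented by the probe set with the highest mean over the 6 arrays among those with exactly 1 symbol, which gave 18193 genes. Ly6a, Ddx3y and Tcf7 had been chosen for reporting and are not analysed here.

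Apcmin was compared with WT with limma 3.58.1 in R (lmFit and eBayes, genotype as the only term), and p-values were adjusted by Benjamini-Hochberg over the 45037 probe sets at a threshold of 0.05. Differences are Apcmin minus WT on the log2 scale. Gene lists were tested with camera at a preset correlation between genes of 0.01 over 24 lists, again adjusted by Benjamini-Hochberg. Camera was repeated with an estimated correlation, and fry was run as a further test. With an estimated correlation camera has only the residual degrees of freedom, 4 with all arrays, and less power. For Wnt components the estimate was -0.009, below the preset value, yet the unadjusted camera p rose from 0.0037 to 0.024. A call lost in that test therefore need not reflect correlation between genes. Camera compares a list with the other genes, whose median difference was -0.04. List members were also adjusted over the list alone, which does not correct for the number of lists. Single values such as control ratios were compared by a two-sided exact permutation test, which cannot go below p = 0.10 with 3 arrays against 3.

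The lists covered Wnt/beta-catenin targets, Wnt pathway components, HSC-associated genes, quiescence and CDK inhibitors, DNA replication, mitosis, the granulocyte and monocyte, lymphoid, erythroid, megakaryocyte and mast cell lineages, mature blood cells, endothelial and stromal cells, interferon response, apoptosis, p53 targets, ribosomal proteins, mouse counterparts of the human 5q deletion, immediate early and heat shock genes, JAK-STAT feedback, Notch and TGF-beta/BMP signalling, Hox genes, adhesion and homing, and energy metabolism. Sex-linked genes were a further list, for which values only are given. The lists, the tests, the rule for named genes and most alternative settings were set before the data were examined.

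The rule named genes past the threshold by size. Where too few passed, it took the 10 genes per direction with the smallest p whose 3 Apcmin values all lay on one side of the 3 WT values and whose higher group had a mean of at least 6. It also took the 2 members of each list with the smallest p in the direction of the list's mean, and a fixed set that includes Apc, Axin2, Lef1, Myc, Ccnd1, Ctnnb1, Kit, Cd34, Flt3, Slamf1, Cdkn1a, Cdkn1c, Mki67, Egr1 and Rps14. Predicted genes were not named.

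The limma step was tested on simulated values with the spread of these arrays over 45037 probe sets. Changes were given only to probe sets with a mean log2 intensity of at least 6. The limma step recovered 0% of probe sets changed 1.5-fold, 7.16% of those changed 2-fold and 91.4% of those changed 4-fold. In simulated lists of 40 genes over 18193 genes, camera called 35.0% of lists shifted by 0.1 on the log2 scale, 95.0% of those shifted by 0.2 and 0 of 420 unshifted lists. Simulated genes were drawn independently, so correlated genes are not covered by that test.

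The alternative settings were filters on dim probe sets, a mean-variance trend, robust moderation, array weights, a further quantile normalization, median centring, the replicate number as a block, leaving out each array, another probe set summary, other thresholds, other set tests, and leaving out sex-linked probe sets. A covariate for Y-linked signal, a floor at a log2 value of 4, and camera with an estimated correlation while leaving out each array, filtering dim probe sets or adding that covariate were added after seeing the data.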

Results

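The data are 6 arrays of LKS+ cells, 3 from WT mice and 3 from Apcmin mice. Apcmin mice carry the Min allele of Apc, a premature stop codon in the gene for a scaffold protein of the complex that targets beta-catenin for degradation. The series title sets out the Apcmin mouse as a model of myeloproliferative and myelodysplastic disease with altered stem cell function. The comparison of the 2 genotypes therefore asks which transcripts differ between Apcmin and WT stem and progenitor cells. After normalization by the authors, the median log2 intensity per array was 4.15 ± 0.03 (SD, n = 3) in WT and 4.15 ± 0.02 in Apcmin, and between 33.3% and 34.5% of probe sets on each array had a log2 intensity of at least 6.

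Apc itself was measured by 4 probe sets. The brightest, which represents the gene, was at 7.72 ± 0.09 (SD, n = 3) in WT and 7.80 ± 0.09 in Apcmin, a difference of 0.08 with a standard error of 0.14 (limma, adjusted p = 0.963). Its 95% confidence interval ran from -0.25 to 0.41. The other Apc probe sets differed by 0.57, 0.40 and -0.01, with an adjusted p of 0.954 or more for each. Min changes a codon and leaves the probed sequence in the transcript, so the Apc mRNA level is a weak check of the genotype labels. Ctnnb1, the gene for beta-catenin, was at 11.63 ± 0.13 in WT and 11.72 ± 0.13 in Apcmin, a difference of 0.09 with an adjusted p of 0.962.

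**Figure D1:**
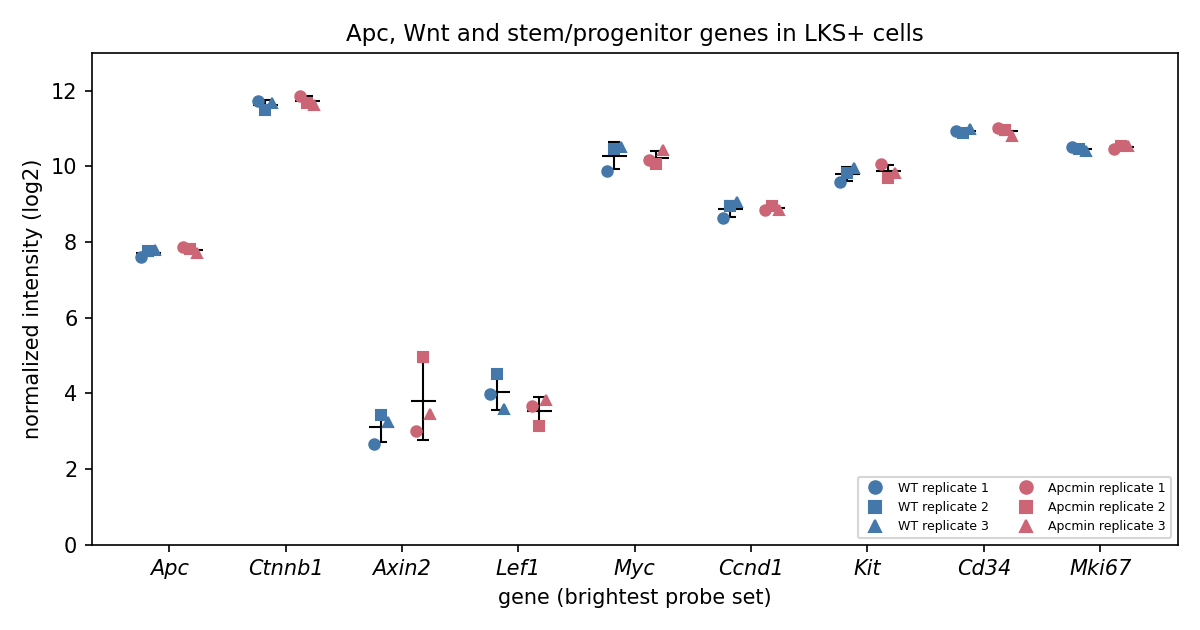
Normalized log2 intensity (vertical axis) of Apc, Wnt-related and stem or progenitor genes (horizontal axis), each from its brightest probe set. Each point is 1 array, blue for WT and red for Apcmin with a marker shape per replicate number, and black bars are the mean and SD of 3 arrays; Apc is at 7.72 in WT and 7.80 in Apcmin, and Axin2 at 3.11 and 3.80.

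Established targets of Wnt/beta-catenin signalling did not pass as a group. Of 32 measured targets, 14 had a higher and 18 a lower mean in Apcmin, with a mean difference of -0.05 and a median of -0.02 (camera, adjusted p = 0.993). Without WT replicate 1 the mean was 0.01 and without WT replicate 3 it was -0.16. Most were dim, since 9 of the 32 had a mean log2 intensity of at least 6 in either genotype. Those 9 had a mean difference of 0.08 and the dimmer targets one of -0.11. Axin2, a feedback inhibitor used as a readout of the pathway, was at 3.11 ± 0.41 in WT and 3.80 ± 1.03 in Apcmin, and Apcmin replicate 2, at 4.97, lay above the other Apcmin values, the higher of which was 3.44. Without that array the Axin2 difference went from 0.69 to 0.11, and the other Axin2 probe set did not go the same way. Lef1, a transcription factor of the pathway, differed by -0.49, Myc by -0.06 and Ccnd1, cyclin D1, by 0.01, and none passed. Ccn4 differed by -0.38 near the bottom of the intensity range, and Nkd1, a further feedback inhibitor, by -0.65 (4.56 ± 0.65 in WT and 3.91 ± 0.21 in Apcmin).

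Genes for components of the Wnt pathway were shifted upward in Apcmin by a small amount. Of 50 measured components, 31 had a higher and 19 a lower mean, with a mean difference of 0.08 and a median of 0.06 (camera, adjusted p = 0.0295). The call was lost with an estimated correlation (adjusted p = 0.575), and with the mean of all probe sets of a gene, where the mean difference was 0.01 (adjusted p = 0.175). Filters at the median and at a log2 mean of 6 (adjusted p = 0.123 and 0.388), the replicate block (0.0558) and a floor at 4 (0.0955) also ended it, as did leaving out WT replicate 2 (0.162), WT replicate 3 (0.0557), Apcmin replicate 1 (0.0661) or Apcmin replicate 3 (0.0544). The mean difference was 0.12 and 0.06 with these filters and 0.08 with the block and with the floor. It stayed between 0.06 and 0.09 when each array was left out. Fzd4, a Wnt receptor, was at 3.76 ± 0.84 in WT and 5.34 ± 0.45 in Apcmin (difference 1.57), and its 2 other probe sets did not go the same way. Kremen1, a receptor for the Wnt antagonists of the Dickkopf family, was at 4.81 ± 0.28 and 5.52 ± 0.16 (difference 0.71). Neither gene passed over all probe sets (adjusted p = 0.954 for both), and 0 of the 50 passed when adjusted over the list alone.

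No gene passed the threshold between the genotypes. In limma 0 of 45037 probe sets had an adjusted p under 0.05, and 0 under 0.10, with 0.954 as the smallest adjusted p. At an unadjusted p under 0.05 there were 1714 probe sets, 3.81% of all where chance gives 5%, of which 751 were higher and 963 lower in Apcmin. Without WT replicate 3 that number was 5864, with 0 past the adjusted threshold. Of 18193 genes, 566 had an unadjusted p under 0.05, 222 higher and 344 lower. In 1406 genes (7.73%) the 3 Apcmin values lay on one side of all 3 WT values, where chance gives 10%. Differences of at least 2-fold were seen in 106 genes, but the 429 probe sets with a difference that large included 16 with a mean log2 intensity of at least 6. The absence of calls does not exclude differences of 2-fold or less. Simulated at this spread, 7.16% of 2-fold and 91.4% of 4-fold changes were recovered among probe sets with a mean log2 intensity of at least 6. Dimmer probe sets were given no changes there, so the simulation does not show which differences would be missed in them.

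The genes with the smallest p among those that separated the groups are given as values, since none passed (adjusted p = 0.954 for each). Among genes higher in Apcmin, Cilk1, a kinase of primary cilia, was at 5.64 ± 0.39 (SD, n = 3) in WT and 6.69 ± 0.29 in Apcmin, a 2.07-fold difference. Nfia, a transcription factor with a role in erythroid and granulocytic differentiation, was at 8.21 ± 0.34 and 8.99 ± 0.20, a 1.72-fold difference, and 3 of its 5 other probe sets went the same way. Rdh10, which makes retinal for retinoic acid synthesis, differed by 0.74, and Tpst1, a tyrosine sulfotransferase, by 0.58. Ammecr1 (0.89), Airn (0.83), Spa17 (0.79), Tmem198b (0.73), Tbccd1 (0.54) and Mob3b (0.51) completed the list of log2 differences. Airn is transcribed antisense to Igf2r, and 2 of its 4 other probe sets went the same way, while the other Mob3b probe set did not.

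Among genes lower in Apcmin, Fcgr2b, the inhibitory Fc gamma receptor, was at 8.33 ± 0.22 in WT and 7.67 ± 0.21 in Apcmin, a difference of -0.66, and all 4 of its other probe sets had the same sign. Itgb2, the common chain of the leukocyte beta2 integrins, was at 7.23 ± 0.22 and 6.72 ± 0.05. Trem3, a myeloid receptor, was at 7.78 ± 0.06 and 7.37 ± 0.06. Fbxo32, a ubiquitin ligase subunit, differed by -0.74, but neither of its 2 other probe sets went the same way. The log2 differences of Tmco3 (-0.67), Ano10 (-0.67), Chn2 (-0.65), Iqcb1 (-0.51), Depdc5 (-0.49) and Brsk1 (-0.45) were of similar size.

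Mitosis genes were shifted upward in Apcmin as a group by a small amount, with 36 of 47 measured members higher and 11 lower. Their mean difference was 0.06 and their median 0.05 (camera, adjusted p = 0.0295), which is a few percent in intensity. With an estimated correlation the call was lost (adjusted p = 0.611), and with the mean of all probe sets of a gene the adjusted p was 0.104. Filters at the median and at a log2 mean of 6 also ended it (adjusted p = 0.191 and 0.292) while the mean difference stayed at 0.06, since camera then compared the list with bright genes alone. Without WT replicate 2, whose mitosis genes deviated most from their mean over the arrays (-0.09), the mean difference was 0.03 (adjusted p = 0.284), and the call was also lost without Apcmin replicate 1 (0.0661) or Apcmin replicate 2 (0.120). The same deviation was -0.02 on Apcmin replicate 3, below 2 of the WT arrays, and no member passed, over all genes or adjusted over the list alone. Bub1, a kinase of the spindle checkpoint, was at 7.99 ± 0.24 in WT and 8.31 ± 0.12 in Apcmin, and Anln, which acts in cytokinesis, at 6.28 ± 0.26 and 6.68 ± 0.21, though the other Anln probe set did not go the same way. Mki67 was at 10.46 ± 0.05 and 10.51 ± 0.05. Genes of DNA replication had a mean difference of 0.06, with 29 of 45 higher, and did not pass (adjusted p = 0.0578), though they did without WT replicate 3 (adjusted p = 0.0168) or Apcmin replicate 2 (0.0467), with a mean-variance trend (0.0303), with array weights (0.0290) and with the Y-linked covariate (0.0478). An estimated correlation ended the calls without those arrays (adjusted p = 0.522 and 0.567) and with the covariate (0.791), and the mean fell to 0.03 without WT replicate 1 (adjusted p = 0.372) or Apcmin replicate 1 (0.252). Orc1, of the origin recognition complex, differed by 0.53 and Mcm5, of the replicative helicase, by 0.30, though neither of the 2 other Mcm5 probe sets went the same way.

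Lymphoid genes were shifted downward in Apcmin, with 28 of 34 measured members lower and 6 higher. Their mean difference was -0.23 and their median -0.24 (camera, adjusted p = 0.0295), and the call was lost with an estimated correlation (adjusted p = 0.611). The shift lay in dim members: the 12 with a mean log2 intensity of at least 6 averaged -0.06 and the others -0.32. With values under 4 set to 4 the mean was -0.08 and the list did not pass (adjusted p = 0.173). The call was also lost without WT replicate 2 (adjusted p = 0.162), WT replicate 3 (0.118), Apcmin replicate 1 (0.0661) or Apcmin replicate 3 (0.271). The mean difference stayed between -0.31 and -0.18 when each array was left out. Filters at the median and at a log2 mean of 6 also ended the call (adjusted p = 0.123 and 0.334). The lymphoid genes' mean deviation from their means over the arrays did not separate the genotypes. It was 0.05 on Apcmin replicate 2 and 0.04 on WT replicate 3 (exact permutation p = 0.20). Markers of mature blood cells that a sort could carry over had a similar mean difference (-0.22, 25 of 33 lower), with each WT array above each Apcmin array (exact permutation p = 0.10), and 6 lymphoid members, Cd3d and Cd79a among them, are also on that list. Cd3d, of the T-cell receptor complex, was at 3.23 ± 0.28 in WT and 2.52 ± 0.43 in Apcmin, and Cd79a, of the B-cell receptor, at 3.85 ± 0.56 and 3.29 ± 0.12. Flt3, a receptor of multipotent and lymphoid-primed progenitors, was bright and differed by 0.05. No member passed, over all genes or adjusted over the list alone. Dim genes as a class were lower in Apcmin, with a median difference of -0.18 over the 4403 genes with a mean between 2 and 4, and WT replicate 1 lay 0.21 above the mean in that class.

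The number of called lists depended on single arrays. It was 3 with all arrays, 0 without WT replicate 2, 0 without Apcmin replicate 1, 1 without Apcmin replicate 3, 6 without WT replicate 1, 5 without Apcmin replicate 2 and 4 without WT replicate 3. With filters at the median and at a log2 mean of 6, 2 lists passed, the granulocyte and interferon lists, and none of the 3 called lists was among them. Leaving out 1 array turned the sign of the mean in 10 of the 24 lists, none of them a called list. Besides the Wnt target, erythroid and interferon lists, and with the most opposite value of each in parentheses, these were Hox (0.01 without WT replicate 2), Notch and TGF-beta/BMP (0.07 without Apcmin replicate 2), apoptosis (0.07 without Apcmin replicate 3), endothelial (0.09 without WT replicate 2), mast cell (0.09 without WT replicate 2), megakaryocyte (0.01 without Apcmin replicate 2) and ribosomal protein genes (-0.01 without WT replicate 2). No list passed with an estimated correlation, whether all arrays were used, each was left out, either filter was applied or the Y-linked covariate was added. That test has few degrees of freedom, so its lack of calls does not show that correlation between genes made the others. No list passed after a further quantile normalization, and with fry 0 passed in the directional and 0 in the mixed test. Genes in 5 lists (quiescence, mast cell, apoptosis, 5q and Notch) had a negative mean while camera ranked them above other genes, and energy metabolism genes had a mean of 0.04 and a median of -0.003.

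**Figure D2:**
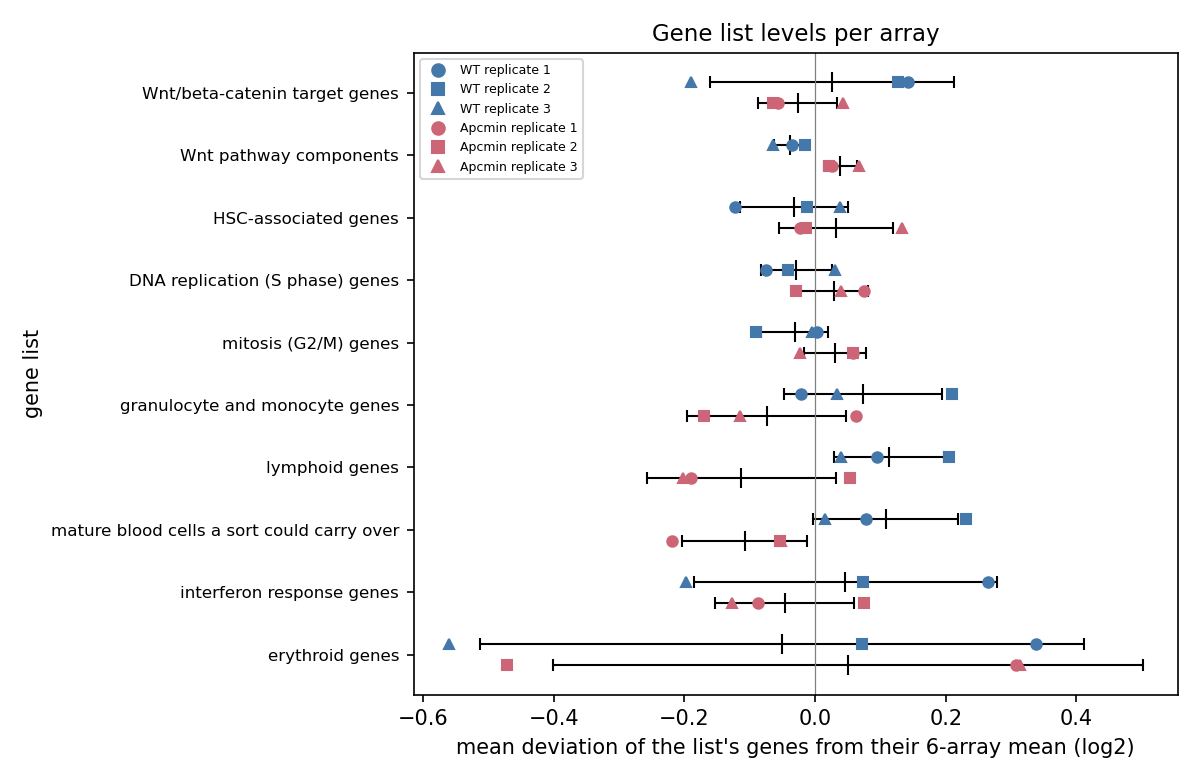
Mean deviation of each list's genes from their mean over the 6 arrays (horizontal axis, log2) for 10 gene lists (vertical axis). Each point is 1 array, blue for WT and red for Apcmin with a marker shape per replicate number, and black bars are the mean and SD of 3 arrays; erythroid genes lie at -0.56 on WT replicate 3 and -0.47 on Apcmin replicate 2 and between 0.07 and 0.34 on the other 4 arrays.

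Stem cell genes did not pass as a group. Of 43 HSC-associated genes measured, 28 were higher and 15 lower in Apcmin, with a mean difference of 0.06 (camera, adjusted p = 0.0790). The list passed without WT replicate 3 (mean 0.10, adjusted p = 0.0168), with a mean-variance trend (0.0475), with array weights (0.0495) and with the Y-linked covariate (0.0411), but with an estimated correlation the first and last of these calls were lost (adjusted p = 0.727 and 0.877). Its mean was 0.02 without WT replicate 1 (adjusted p = 0.827) and 0.01 without Apcmin replicate 3 (0.415). Clec1a differed by 1.02 and Zfp521, a zinc finger protein of immature blood cells, by 0.48. Kit, the receptor used in the sort, was at 9.79 ± 0.18 in WT and 9.87 ± 0.18 in Apcmin, and Cd34 was at 10.94 ± 0.05 and 10.94 ± 0.11. Slamf1 differed by -0.22. Quiescence and CDK inhibitor genes had a mean difference of -0.03 (adjusted p = 0.993), with -0.44 for Tsc1, an inhibitor of mTOR signalling, and -0.71 for Cdkn2b, which is near the floor. Cdkn1a differed by -0.20 and Cdkn1c by -0.11.

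Among the other lineage lists, granulocyte and monocyte genes had 28 of 36 members lower in Apcmin with a mean difference of -0.15, and did not pass (adjusted p = 0.150). They passed with filters at the median (mean -0.10, adjusted p = 0.0345) and at a log2 mean of 6 (mean -0.11, adjusted p = 0.00538), which an estimated correlation ended (adjusted p = 0.725 and 0.389). They also passed with a mean-variance trend (adjusted p = 0.0303), with a floor at 4 (0.00232) and without WT replicate 1 (0.00630, or 0.793 with an estimated correlation), while without WT replicate 2 the mean was -0.08 (0.380). The 28 members with a mean log2 intensity of at least 6 averaged -0.11, with each WT array above each Apcmin array. That separation was noticed after the values were seen. Cd14, a monocyte receptor, differed by -1.02 at a dim level, and Hk3 was at 8.58 ± 0.33 in WT and 8.15 ± 0.11 in Apcmin. Megakaryocyte and platelet genes had a mean difference of -0.07 (adjusted p = 0.974), with -0.88 for Rab27b, none of whose 3 other probe sets went the same way, and -0.70 for Gp6, which was near the floor. Mast cell and basophil genes had a mean near 0 (-0.002, adjusted p = 0.993), with -0.25 for Fcer1g and -0.32 for Gzmb. Markers of mature blood cells that a sort could carry over had 25 of 33 members lower and a mean difference of -0.22 without passing (adjusted p = 0.107), though they passed with array weights (adjusted p = 0.0249) and without WT replicate 1 (0.00412, or 0.872 with an estimated correlation) or Apcmin replicate 2 (0.0487, or 0.865), and Marco, a macrophage receptor, differed by -0.48. Endothelial and stromal genes had a mean difference of -0.03 (adjusted p = 0.993), with -0.54 for Alpl and -0.46 for Sparc.

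Erythroid genes varied more between arrays than between genotypes. Of 33 measured members, 25 had a higher mean in Apcmin, with a mean difference of 0.10 and a median of 0.15 (camera, adjusted p = 0.133). Without WT replicate 3 the mean difference was -0.15, without Apcmin replicate 1 it was -0.03 and without Apcmin replicate 3 also -0.03. It was 0.36 without Apcmin replicate 2 (adjusted p = 7.49e-06), 0.29 without WT replicate 1 (adjusted p = 0.000446) and 0.16 without WT replicate 2. With an estimated correlation neither fit passed (adjusted p = 0.865 without Apcmin replicate 2 and 0.872 without WT replicate 1), and with all arrays the adjusted p was 0.996. With the Y-linked covariate the list passed (adjusted p = 0.0235), and this call was lost with an estimated correlation (adjusted p = 0.791). Rhag, a red cell membrane protein, differed by 0.89 and Icam4 by 0.55. Slc4a1, the red cell anion exchanger, was at 4.46 in WT and 2.98 in Apcmin and went against the list, with all 3 Apcmin values below the WT values. It passed when adjusted over the list alone (adjusted p = 0.0247) and did not pass over all genes. Slc4a1 was named after its values were seen.

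In signalling lists, Jag1, a Notch ligand, was the member that stood out, and it had the smallest p of all genes. It was at 3.68 in WT and 4.83 in Apcmin, a difference of 1.15 with a standard error of 0.17, and all 3 Apcmin values lay above the WT values. It passed when adjusted over the list alone (adjusted p = 0.0105), without a correction for the number of lists. It did not pass over all genes (adjusted p = 0.954). Jag1 was dim in both genotypes and was named after its values were seen. The 39 Notch and TGF-beta/BMP genes together had a mean difference of -0.01 (adjusted p = 0.993), with -0.61 for Dll1 and -0.59 for Id1. JAK-STAT and cytokine feedback genes had a mean difference of 0.04 (adjusted p = 0.160), passing with array weights (adjusted p = 0.0495) and without WT replicate 3 (mean 0.10, adjusted p = 0.0177, or 0.522 with an estimated correlation) but with a mean of 0.001 without WT replicate 2 (0.861), with 0.56 for the kinase gene Pim2 and 0.58 for Spry1. Hox and cofactor genes had a mean difference of -0.04 (adjusted p = 0.993), with -0.50 for Hoxb9 and -0.36 for Cdx1, both dim. Adhesion and homing genes had a mean difference of -0.06 (adjusted p = 0.944), with Itgb2 as above and -0.67 for Itga2.

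Stress, survival and housekeeping lists did not pass with all arrays and probe sets. Interferon response genes had 24 of 36 members lower and a mean difference of -0.09 (adjusted p = 0.479). They passed with filters at the median (mean -0.14, adjusted p = 0.0345) and at a log2 mean of 6 (mean -0.14, adjusted p = 0.00538) and with a floor at 4 (0.0223), and with an estimated correlation neither filter kept the call (adjusted p = 0.852 and 0.900). Without WT replicate 1 the sign turned (mean 0.02, adjusted p = 0.914), and without WT replicate 3 the mean was -0.22 (0.131). Examples were -0.29 for Igtp and -0.63 for Mx1. Immediate early and heat shock genes had a mean difference of -0.11 (adjusted p = 0.974), which was -0.02 without Apcmin replicate 1, with -0.66 for Klf4, whose other probe set did not go the same way, and -1.47 for Hspa1b, whose SD in Apcmin was 1.68. Egr1 was at 9.84 ± 0.32 in WT and 9.97 ± 0.34 in Apcmin. Apoptosis regulators had a mean difference of -0.0004 (adjusted p = 0.955), with -0.47 for Bok and -0.66 for Pmaip1. p53 targets had a mean difference of -0.06 (adjusted p = 0.974), with -0.35 for Plk3 and -0.33 for Ddb2, whose other probe set did not go the same way. Mouse counterparts of genes in the human 5q deletion, a region lost in some myelodysplastic syndromes that holds APC, had 20 members higher and 20 lower (mean -0.05, adjusted p = 0.993), with -0.35 for Lect2. Rps14, of that list, was at 12.14 ± 0.07 and 12.12 ± 0.06. Ribosomal protein genes had a mean difference of 0.02 (adjusted p = 0.244), with 0.33 for Rps25 and 0.25 for Rps4l. Energy metabolism genes did not pass (adjusted p = 0.152), with 0.45 for Ppargc1b and 0.22 for Hk2.

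The arrays differed in ways the genotype does not set. WT replicate 1 had a median correlation of 0.975 with the other arrays, across probe sets, where the other 5 arrays had 0.983 to 0.987. The log2 ratio of the 3' to the 5' control probe sets was 0.90 ± 0.06 (SD, n = 3) in WT and 0.95 ± 0.04 in Apcmin for Gapdh (exact permutation p = 0.30), and 0.81 ± 0.10 and 0.89 ± 0.02 for beta-actin (exact permutation p = 0.20). Xist, the RNA that silences an X chromosome, was between 10.63 and 10.74 on 4 arrays, 2.48 on WT replicate 3 and 3.14 on Apcmin replicate 2. On those same 2 arrays the Y-linked genes Kdm5d (7.13 and 6.79), Eif2s3y (9.20 and 9.39) and Uty (5.62 and 4.93) were bright, while on the other 4 arrays none of these genes exceeded 1.58. Each genotype thus held 1 array with Y-linked signal, and none of the 4 measured sex-linked genes passed between the genotypes.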

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

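Counts past the adjusted threshold were 0 for probe sets and 0 for genes under each alternative, with the smallest adjusted p between 0.333 (without WT replicate 3) and 1. The Y-linked covariate, the floor at 4 and the estimated correlation with an array left out, a filter or the covariate were the tests chosen after the results were seen. The combined threshold of an unadjusted p under 0.01 and a 1.5-fold difference gave 226 probe sets and 66 genes, as it does not correct for the number tested. Probe sets with an unadjusted p under 0.05 numbered 1714, against 757 and 486 after filters at the median and at a log2 mean of 6, where fewer were tested. They numbered 2717 with array weights, 911 with the floor, and 1267 to 5864 when each array was left out. Called gene lists numbered 3, against 6 with a mean-variance trend, 7 with array weights, 0 after a further quantile normalization, 1 with the mean of a gene's probe sets, 0 with an estimated correlation (with all arrays, with each array left out, with either filter or with the covariate), 0 and 0 with fry (directional and mixed), 6 with the Y-linked covariate, and 0 to 6 when each array was left out. Except for the filters, the cause was not tested. The Apc difference stayed between 0.02 and 0.26 and never passed. The replicate numbers did not pair the arrays. Across probe sets with a mean log2 intensity of at least 6, the deviations of same-numbered arrays had correlations of 0.05, -0.05 and -0.25. No WT array correlated best with the Apcmin array of its own number. The replicate block gave 0 probe sets, 1398 with an unadjusted p under 0.05, and 2 lists. Signal over background limits lists with dim members, such as the lymphoid and Wnt target lists.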

Other observations

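The tests of the pattern with Y-linked signal (other than that of late red cell genes), the labelling and degradation tests of WT replicate 1, both tests of the Wnt component list, the carry-over test of the lymphoid list and, after its outcome, the demand that its bright genes separate the groups too, the comparison of matched lists with uncalled lists, the floor at 4, and the splits of the arrays for probe sets and genes were chosen only after the result was seen. Erythroid genes were lower on the 2 arrays with Y-linked signal, WT replicate 3 and Apcmin replicate 2, than on the other 4 arrays. With genotype as a covariate, 31 of 33 members had a lower mean, by -0.77 on average, with -0.77 among the WT and -0.78 among the Apcmin arrays. On both arrays 24 of the 33 members (72.7%) lay below all 4 others, against 10.4% of all genes and 6.67% by chance. Klf1 and Gata1, transcription factors of red cell development, differed by -1.57 and -0.91, Epor, the erythropoietin receptor, by -1.48, and Aqp1, Ermap and Car1 by -1.54, -1.52 and -0.99. None of them passed over all probe sets (smallest adjusted p = 0.213), while the 13 probe sets that passed included 7 of Xist, Eif2s3y, Kdm5d and Uty and 6 without a gene name here. The list had an adjusted p of 5.7e-21 by camera at the preset correlation and of 0.393 with an estimated correlation. The exact permutation p was 0.0667, the smallest that 15 splits of 2 against 4 arrays can give, and the megakaryocyte list reached it too. Of the 33 members 3 are also on another list, and 20 had a mean log2 intensity of at least 6. The pattern was noticed among 24 lists in the same data.

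A general lack of Sca-1-negative progenitors on those 2 arrays stays open. Granulocyte and monocyte genes with a mean of at least 6 differed by -0.017, which goes against it. However, that whole list differed by -0.10 with 25 of 36 members lower, and megakaryocyte and platelet genes by -0.18 with 18 of 31 lower. A weaker labelled sample on both arrays with Y-linked signal was not seen on the BioB and BioC controls, spiked in at a fixed amount. These averaged 9.64 on WT replicate 3 and 9.76 on Apcmin replicate 2, within the 9.49 to 10.18 of the other 4 arrays. The lower of the 2 arrays lay -0.537 from the highest of the other 4, which spanned 0.688, so a small difference in labelling stays open. Maturing red cells carried over on the other 4 arrays stay open, since the late members differed by -0.810 and the early ones by -0.867 but only 2 late members were bright enough to use, while Alas2 lay between 1.70 and 2.36 on all 6 arrays; a lineage gate would remove most such cells. No biological explanation was tested, and the sex of the animals, their age and the day of the sort may each account for it.

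WT replicate 1 stood apart from the other 5 arrays on the first principal component, at -88.5 against -24.4 to 40.4, and its 18S 3' control was at 8.63 against 6.58 to 6.97. Mature blood cells carried over in that sort are argued against by their genes with a mean of at least 6, which deviated by -0.212 on that array; 11 of the 33 were that bright and 12 are also on another list. A weaker labelled sample may have contributed, since its BioB and BioC controls lay 0.328 above the highest of the other arrays, but those 5 spanned 0.360. The 3' to 5' controls gave no sign of RNA more degraded on that array than on all others. Its log2 ratios were 0.98 for Gapdh and 0.90 for beta-actin, against 0.98 and 0.90 on Apcmin replicate 2 and 0.97 and 0.91 on Apcmin replicate 3. Its beta-actin ratio differed by -0.0109 from the highest of the others. These ratios do not separate that array, and degradation that they miss stays open. No biological explanation was tested.

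The shifts of called lists could come from that array, from brightness or, for lymphoid genes, from carried-over cells. That array is argued against as their whole source, since without it the mean difference was -0.234 for lymphoid genes, 0.0792 for Wnt components and 0.0783 for mitosis genes, where its own mean deviation (0.002) was the highest of the WT arrays and WT replicate 2 (-0.09) the lowest. A raised floor of dim probe sets on the WT arrays stays open for the lymphoid shift: its mean lay at percentile 0.05 of 10000 random lists matched on mean level, but 5 of 21 uncalled lists also lay outside the middle 95% of theirs where chance gives 1.05, so that percentile does not exclude it, and a floor at 4 left a mean of -0.08. Mature blood cells carried over in the WT sorts stay open too: 16 of their genes that are not on the lymphoid list and have a mean of at least 4 differed by -0.200 (standard error 0.126), each WT array above each Apcmin array, but the 11 genes of the whole list with a mean of at least 6 differed by -0.07 without such a separation, S100a9 and S100a8 by -0.07 and -0.05, and a lineage gate would remove most such cells. Among those uncalled lists, granulocyte and monocyte genes lay at percentile 0, below the lymphoid list. An uncalled list is thus not a list known to be unshifted. The Wnt component shift lay at percentile 98.9, and those uncalled lists weaken that percentile too. The random lists matched to it had a median of -0.0133 against its mean of 0.0772, the opposite sign. Lists of similar brightness thus showed no rise on average. The weakened percentile cannot tell whether the Wnt component list lies beyond the spread of such lists. A shift shared by probe sets of similar brightness therefore stays open for it. The mitosis shift lay at percentile 95.7, within the middle 95% of its matched lists. Their median was 0.0238 against a list mean of 0.0617. A shift shared by probe sets of that brightness could thus account for part of it, and the percentile does not set the remainder apart. Genotype stays open for the 3 lists.

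With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The genotype split gave 0 probe sets past the threshold where the highest other split gave 1, and 0 genes where the highest other gave 0, so all 10 splits gave as many. It gave 1714 probe sets with an unadjusted p under 0.05 where the highest other gave 6227, and 5 of the 10 splits gave as many. It gave 3 gene lists where the highest other gave 4, and 6 of the 10 splits gave as many. The split with 6227 set WT replicates 1 and 2 with Apcmin replicate 3 against the rest. It was picked as the largest of the 10 after the counts were seen, which ranged from 964 to 6227. Like the genotype split it gave 0 probe sets past the threshold and 3 lists. It runs along the first principal component. There WT replicates 1 and 2 and Apcmin replicate 3 lay at -88.5, -24.4 and 6.63, and the other arrays between 32.5 and 40.4. What lies behind that variation between the arrays was not tested.

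A further hypothesis was that a chromosome segment linked to the Min allele would leave differences in genes next to Apc. Among the 50 protein-coding genes on each side, 90 had a value, and 2 of them (2.22%) had an unadjusted p under 0.05, against 3.12% of 18102 other genes. The one-sided Fisher's exact p was 0.775, so no excess was seen.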
